A study of Mus musculus with 8 samples.

How the data were processed

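RNA was measured in bone marrow derived macrophages, which are macrophages grown in culture from the bone marrow cells of mice. Per the labels, the 8 libraries fall into 4 controls, whose Abca1 and Abcg1 alleles were flanked by recombination sites, and 4 knockouts, which carried the same alleles together with LysM-Cre, a recombinase gene inserted at the lysozyme gene Lyz2 and active in myeloid cells. The labels describe the animals as littermates matched for sex. They number the libraries 1 to 4 in each group and do not say whether each library came from its own animal, so the p-values measure the spread between these libraries. Per the labels' protocols, cells were lysed in TRIzol, RNA was purified on columns, and cDNA was amplified with SMARTer chemistry.

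Gene counts were deposited as estimated counts, which the authors left without normalization. The submitters' processing notes name bcl2fastq, DRAGEN, edgeR, limma and the build GRCm38. The versions, the annotation release and the strand setting are not given in the sources used here. Of the genes, 13.9% held a fractional value in at least 1 library, and values were rounded to whole numbers for the count models. The table had 55774 rows, of which 287 repeated a gene identifier with identical values and were removed, leaving 55487 genes. No row lacked a gene name. A second deposited table gives the authors' own comparison, with log2 fold changes, p-values, and limma scores and statistics for 11985 genes. It was used only for the comparison of calls. Coordinates, GC content and length were taken from GENCODE M21 on GRCm38, in which 55141 genes (99.4%) were found by identifier.

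The knockout libraries were compared with the controls by edgeR's quasi-likelihood F test with robust estimation, TMM scaling and the default expression filter on the group. The model held the group alone. p-values were adjusted by the Benjamini-Hochberg method over the 13857 genes tested, with a threshold of 0.05. A standard error is the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, the counts divided by TMM-scaled library sizes and put on the usual common scale, given as mean ± SD. Sums over a gene list instead use total counts without TMM scaling and include members too low to be tested. The interferon sums of single libraries are the exception, with TMM scaling and tested members only. Without strand information, reads of overlapping and antisense genes cannot be told apart, and reads of close paralogs or pseudogenes may have been split by the authors' counting.

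Before the data were examined, 27 gene lists were written by hand. They cover LXR targets, cholesterol synthesis, fatty acid synthesis, cholesterol uptake and storage, other ABC transporters, inflammatory, inflammasome, interferon, alternative activation, ER stress, lysosome, lipid-associated macrophage, cell cycle, MHC class II, macrophage identity, immediate early and glycolysis genes, and markers of 10 other kinds of cell. The 20 lists with at least 5 tested members were compared with the remaining genes by limma's camera on log2 CPM (prior count 2, two-sided, preset correlation between genes 0.01), with Benjamini-Hochberg adjustment over the lists. camera with an estimated correlation and fry were run as alternatives. Named genes were also chosen by a rule set at that time. It takes Abca1, Abcg1 and Lyz2, the 10 largest log2 fold changes in each direction among called genes with a mean log2 CPM above 1, groups that do not overlap and a symbol that is not a predicted or clone name, and up to 4 members of each list with the smallest p-values, with every called member where there were 5 or fewer. Genes outside the rule are marked where they appear. A single gene among those that the rule names was left out and is not reported here.

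Other settings were DESeq2, limma voom with and without sample quality weights, other scalings, other filters, stricter thresholds, the replicate number as a block, a surrogate variable, and leaving out each library. After the data were examined, 3 were added, namely the sex of each library as a covariate, an offset that removes each library's smooth trend with GC content (a spline with 5 degrees of freedom), and both together. Sex was read from the counts of Xist, which is expressed from the inactive X chromosome, and of 4 Y-linked genes. Measures of single libraries were compared by two-sided exact permutation tests, for which 0.0286 is the smallest p that 4 against 4 libraries can give, with adjustment over 10 measures.

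The count model was tested on simulated data, drawn for the same 13857 genes with the means and library sizes of this comparison. It recovered 44.9% of 49 genes changed by 1.5-fold, and 84.0%, 84.0% and 86.0% of 50 genes each changed by 2-, 3- and 4-fold. In all 235 genes had been changed, list members included, and 4.92% of the calls fell on genes that had not been. Both changed gene lists were recovered, and 0 of 17 others were called. Each gene was drawn independently, without correlation between genes, sex differences or a GC trend. The simulation therefore cannot show how often lists of correlated genes are called by chance. The total counts ranged from 7609216 to 40097211, at which 3 counts correspond to 0.394 and 0.0748 CPM. Amplified reads without molecular identifiers are not independent molecules, so such floors cover counting error only. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.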

Results

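Messenger RNA levels were compared between bone marrow derived macrophages of 4 control and 4 Abca1/Abcg1 knockout libraries, to ask how loss of these cholesterol efflux transporters in myeloid cells changes the expression of other genes. Controls 1 to 4 held 15890379, 33949483, 24470082 and 27596995 counts and knockouts 1 to 4 held 34695317, 40097211, 26502024 and 7609216, so knockout 4 was the shallowest library. Pearson correlations of log2 CPM across genes were 0.978 to 0.989 between controls and 0.985 to 0.990 among knockouts 1 to 3, against 0.967 to 0.974 between knockout 4 and any other library. The groups were unequal in sex by their counts of Xist and 4 Y-linked genes, although the labels describe matched animals. Control 1 and knockouts 1 to 3 were male, with 0 Xist counts and 3863 to 9303 Y-linked counts. Controls 2 to 4 and knockout 4 were female, with 1594 to 6375 Xist counts and at most 1 Y-linked count. Females were thus 3 controls and 1 knockout, and males 1 control and 3 knockouts.

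Both targeted transporters were lower in the knockout libraries. Abcg1, which exports cholesterol to high density lipoprotein, fell from 376 ± 44.4 to 122 ± 35.6 CPM (SD, n = 4 each), and Abca1, which loads cholesterol onto apolipoprotein A-I, fell from 67.8 ± 19.9 to 31.3 ± 4.72 CPM. All 4 knockout libraries lay below all 4 controls for both genes. Among females Abcg1 was at 364 CPM in controls and 70.0 CPM in the knockout, and among males at 409 and 139 CPM. Single libraries held 409, 351, 326 and 417 CPM of Abcg1 in controls 1 to 4 and 135, 152, 130 and 70.0 CPM in knockouts 1 to 4. For Abca1 the values were 96.7, 63.5, 59.6 and 51.5 CPM in the controls and 33.9, 29.1, 36.4 and 25.9 CPM in the knockouts. Lyz2, the lysozyme gene that carries the Cre insertion, fell from 55380 ± 2306 to 24750 ± 984 CPM. The log2 fold changes by edgeR's quasi-likelihood test were −1.62 for Abcg1 (SE 0.22, adjusted p = 0.0147), −1.10 for Abca1 (SE 0.19, adjusted p = 0.0195) and −1.16 for Lyz2 (SE 0.10, adjusted p = 6.59e-06). Abca1 (ENSMUSG00000015243) lies on chromosome 4 at 53030787 to 53159895, Abcg1 (ENSMUSG00000024030) on chromosome 17 at 31057675 to 31117988 and Lyz2 (ENSMUSG00000069516) on chromosome 10 at 117277331 to 117282321 (GRCm38, whole gene spans). The counts cover whole genes, so transcripts that lack only deleted exons still contribute to them. With sex as a covariate, edgeR gave log2 fold changes of −1.94 for Abcg1 and −1.39 for Abca1 (adjusted p = 0.000834 and 6.63e-06). Without control 2, knockout 2 or knockout 3, the adjusted p of Abca1 was 0.0607, 0.0692 and 0.0621, and without control 2 or knockout 3 that of Abcg1 was 0.0556 and 0.0683.

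**Figure D1:**
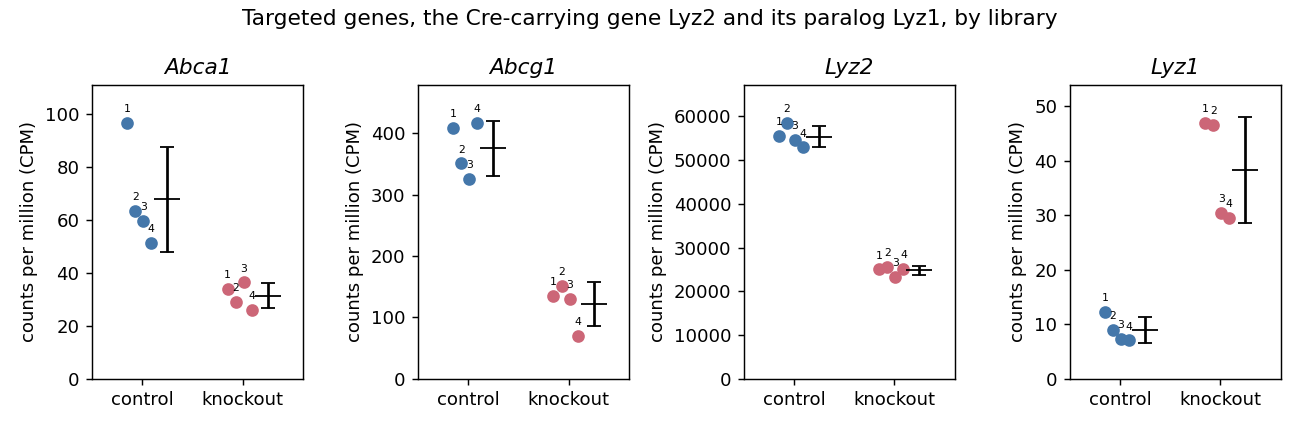
CPM, the counts scaled to a common library size (vertical axes, from 0), of Abca1, Abcg1, Lyz2 and Lyz1 in each library, with points numbered by replicate and black bars for the group mean ± SD (n = 4). Abca1, Abcg1 and Lyz2 were lower in all 4 knockout libraries than in all 4 controls, and Lyz1 was higher, at 29.5 to 46.8 CPM against 7.01 to 12.3 CPM.

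Beyond the targeted genes, the knockout macrophages carried more transcript of the adhesion molecule Vcam1, of the lipid-related genes Cd5l and Apoc1, of Lyz1 and of the glycolytic enzyme Hk2. Cd5l, a secreted scavenger receptor family protein of tissue macrophages, rose from 19.1 ± 4.61 to 66.8 ± 5.16 CPM (SD, n = 4 each), a log2 fold change of 1.79 (SE 0.15, edgeR adjusted p = 3.22e-05). Vcam1, which binds integrins on leukocytes, rose from 4.70 ± 2.66 to 23.3 ± 1.69 CPM (log2 fold change 2.26, SE 0.41, edgeR adjusted p = 0.0422). Hk2, the first enzyme of glycolysis, rose from 24.0 ± 2.51 to 49.4 ± 6.61 CPM (1.05, SE 0.11, edgeR adjusted p = 4.33e-05). Apoc1, an apolipoprotein and LXR target, rose by 1.63 on the log2 scale from 1.53 CPM, and Tmem154, a membrane protein gene, by 1.36 from 27.3 CPM. The chemokine Ccl5 rose from 91.5 ± 18.0 to 156 ± 26.3 CPM (0.77), and the metalloproteinase Mmp27, Dzip3 and the phosphodiesterase Pde1c rose by 1.04, 0.91 and 0.78. Lyz1, the paralog that lies next to Lyz2, rose from 8.90 ± 2.41 to 38.3 ± 9.69 CPM (2.13, SE 0.21, edgeR adjusted p = 0.00144). This value is uncertain, because reads of the 2 near-identical lysozyme genes can be counted for either. Cd5l (ENSMUSG00000015854) lies on chromosome 3 at 87357881 to 87371073, Vcam1 (ENSMUSG00000027962) on chromosome 3 at 116109949 to 116129688 and Lyz1 (ENSMUSG00000069515) on chromosome 10 at 117287797 to 117292868. With the sex covariate, Dzip3 alone among these 10 genes missed the threshold (0.98, edgeR adjusted p = 0.0932), as it did with the GC offset (0.80, 0.0621), while Vcam1, Tmem154, Dzip3 and Ccl5 missed it with both. The calls of Lyz1, Cd5l, Apoc1, Tmem154, Hk2 and Mmp27 held whichever library was left out, but that of Ccl5 was lost without control 2, control 3 or knockout 3, that of Pde1c also without knockout 2, that of Dzip3 without any library except control 1 or knockout 4, and that of Vcam1 without any except control 1 or control 4.

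The signalling adapter Dok2, which restrains tyrosine kinase signalling in myeloid cells, had the largest of the 10 named falls, from 48.8 ± 8.67 to 19.3 ± 2.63 CPM (SD, n = 4 each; log2 fold change −1.33, SE 0.13, edgeR adjusted p = 4.33e-05). Atp5d, a subunit of ATP synthase, fell from 53.1 ± 11.0 to 28.3 ± 4.02 CPM (−0.90), Mrpl54, a mitochondrial ribosomal protein, from 23.4 ± 3.37 to 12.6 ± 3.06 CPM (−0.88), and Polrmt, the mitochondrial RNA polymerase, from 3.03 ± 0.660 to 1.64 ± 0.291 CPM (−0.90). Osgep, of the complex that modifies transfer RNA, changed by −0.91, the mitochondrial hydrolase Hint2 by −0.95, and Klhl26, Tpgs1 and Tlnrd1 by −1.11, −0.93 and −0.93. The histone gene H2ac19 changed by −1.09 and has near-identical copies that can share its reads. With the sex covariate only Dok2 of these 10 stayed past the threshold (−1.22, edgeR adjusted p = 0.00241). The log2 fold changes of Atp5d and Mrpl54 were then −0.88 and −0.90, with adjusted p of 0.0580 and 0.0564. Those of Polrmt, Osgep and Tlnrd1 were −1.04, −0.94 and −0.93, while those of Klhl26, Hint2, H2ac19 and Tpgs1 were nearer 0, at −0.96, −0.76, −0.65 and −0.62. The calls of H2ac19, Hint2, Tpgs1 and Polrmt were also lost with the GC offset, at −0.74, −0.86, −0.62 and −0.67. Those of Atp5d and Mrpl54 were kept with that offset at smaller sizes, −0.69 and −0.63 (edgeR adjusted p = 0.00475 and 0.0236). The calls of Dok2, Atp5d and Mrpl54 held whichever library was left out, while the other 7 were lost without control 2 or control 3, and all of these except Tlnrd1 also without some knockout library. The GC content of Atp5d, Mrpl54, Polrmt and Tpgs1 was 59.3%, 60.8%, 60.2% and 63.0%, against a median of 49.2% over all tested genes.

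**Figure D2:**
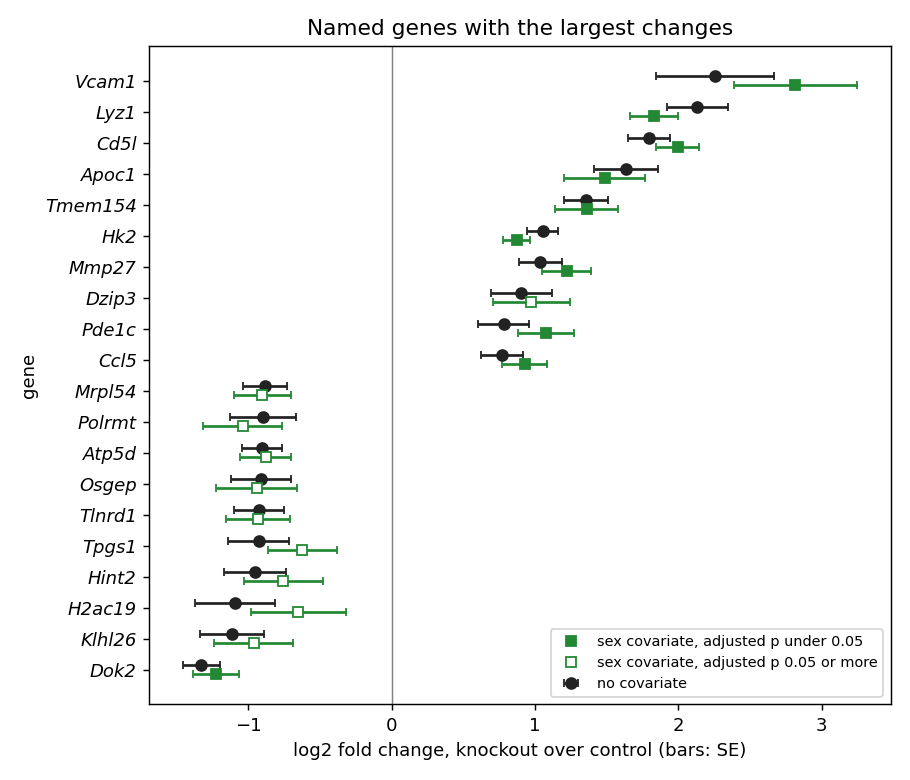
Log2 fold change, knockout over control (horizontal axis), of the 10 largest rises and falls under the naming rule, with bars for the standard error. Black circles come from the model without a covariate and green squares from the model with sex, filled where the adjusted p is under 0.05. The square of Dok2 at −1.22 is the only filled square among the falls.

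In all, edgeR called 380 of 13857 genes at an adjusted p under 0.05, of which 212 were higher and 168 lower in the knockouts. The changes were mostly modest, with a median absolute log2 fold change of 0.52 among called genes. Only 35 genes rose and 11 fell by over 2-fold. Over all tested genes, the groups did not overlap in 1364 (9.84%), where chance gives 2.86%. With total counts as the only scaling the split was 282 higher and 115 lower, or 71.0% higher against 55.8%. The sex covariate left 50 higher and 41 lower, of which 68 were among the 380. Without control 2, 39 genes were higher and 13 lower, without control 3 44 and 32, without knockout 1 148 and 96, without knockout 2 64 and 48, and without knockout 3 50 and 25. Without control 1, 327 were higher and 352 lower, and without knockout 4 404 and 241. The authors' deposited table called 1596 of 11985 genes at 0.05, with 843 higher and 753 lower. It shared 366 of the 380 calls, all with the same sign, and its log2 fold changes had a Pearson correlation of 0.848 with those of edgeR across genes, which are not independent replicates.

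A few genes of sterol and lipid handling passed the test singly, and none of the 5 lists was called by camera with all libraries. Among the 15 tested LXR target genes, which answer to oxysterol-activated LXR receptors, Cd5l and Apoc1 rose, Srebf1 fell and 12 did not pass edgeR's test. Srebf1, the transcription factor of fatty acid synthesis, fell from 7.49 ± 1.69 to 4.28 ± 0.902 CPM (SD, n = 4 each; log2 fold change −0.82, edgeR adjusted p = 0.0323). With p-values adjusted over the list alone, 3 LXR targets were higher, Apoc2 (0.31) included, and 1 was lower. Of 24 cholesterol synthesis and SREBP2 target genes, only Insig1, which retains SREBP in the endoplasmic reticulum, rose, from 31.4 ± 3.69 to 45.6 ± 1.17 CPM (0.54, edgeR adjusted p = 0.00742), also when adjusted over the list alone. Nsdhl and Sc5d, both sterol synthesis enzymes, had log2 fold changes of 0.25 and 0.20 that did not pass. Of 12 fatty acid synthesis genes only Srebf1 fell, also adjusted over the list alone, with Fads1, Acaca and Elovl6 at −0.24, −0.34 and −0.45. Among 22 uptake, storage and trafficking genes Plin2, the lipid droplet coat protein, rose from 4070 ± 671 to 5602 ± 288 CPM (0.46, edgeR adjusted p = 0.0317). Lrp1 (−0.32) passed too when adjusted over the list alone, while Vps4b and Npc2 were at −0.29 and 0.26. None of 21 other ABC transporter genes passed edgeR's test over all genes, against 6 at an unadjusted p under 0.05, 3 called by DESeq2, 1 by limma voom and 5 by voom with sample quality weights. There were 2 higher and 3 lower adjusted over the list alone, with Abcc5, Abcd2, Abca7 and Abcb10 at 0.41, 0.35, −0.50 and −0.59. By camera, the adjusted p of these 5 lists ran from 0.166 for the SREBP2 list, with 18 of 24 genes at a positive log2 fold change, to 0.868 for uptake and storage. In sum, controls and knockouts held 6347 ± 573 and 5615 ± 411 CPM of LXR targets, 507 ± 32.6 and 579 ± 44.6 CPM of SREBP2 genes, and 364 ± 19.8 and 374 ± 8.89 CPM of fatty acid synthesis genes. Uptake and storage genes summed to 12360 ± 1058 and 15180 ± 545 CPM, and other ABC transporters to 795 ± 28.8 and 814 ± 50.7 CPM, and none of these sums was tested. camera called the SREBP2 list without control 1 (adjusted p = 0.0266) or knockout 3 (adjusted p = 0.00481). The calls of Srebf1 and Plin2 were lost without control 2, control 3, knockout 2 or knockout 3, and that of Plin2 without knockout 1. That of Srebf1 was also lost with the sex covariate or the GC offset (−0.87 and −0.61, edgeR adjusted p = 0.0918 and 0.0660), and that of Insig1 with both together.

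All 28 tested type I interferon-stimulated genes, the antiviral program induced by interferon, had a positive log2 fold change, with a median of 0.29. The set lay above other genes by camera with the preset correlation (adjusted p = 1.56e-05), but not with an estimated correlation (adjusted p = 0.657). By fry, the adjusted p of this list was 0.336. None of the 28 passed edgeR's test singly, over all genes or adjusted over the list alone, against 13 at an unadjusted p under 0.05, 3 called by DESeq2, 0 by limma voom and 10 by voom with sample quality weights. Zbp1, a nucleic acid sensor, went from 99.2 ± 8.66 to 132 ± 25.7 CPM (0.41, SE 0.12, edgeR adjusted p = 0.0788), and Rtp4, Oasl2 and Ddx58 were at 0.33, 0.30 and 0.31. The summed level of the 28 genes was 5846 to 6766 CPM in the controls, and 6420, 8919, 9743 and 6845 CPM in knockouts 1 to 4, so knockout 1 lay within the control range and knockout 4 just above it. Of 18 inflammatory genes induced through NF-kB, Ccl5 alone passed edgeR's test over all genes. DESeq2 called 1 higher and 2 lower, limma voom 1 and 0, and voom with sample quality weights 1 and 4. Il1b, Nfkbia and Cxcl2 had log2 fold changes of −0.70, −0.35 and −0.49 that did not pass edgeR's test. Adjusted over the list alone, 1 was higher and 2 were lower (camera adjusted p = 0.205). Among 16 inflammasome genes Nlrc4, a sensor adapter, rose from 22.1 ± 0.951 to 29.7 ± 2.06 CPM (0.42, edgeR adjusted p = 0.0214), and Txnip, which binds thioredoxin, fell from 483 ± 42.1 to 390 ± 9.95 CPM (−0.31, edgeR adjusted p = 0.0464). Il18 was at 0.37. Adjusted over the list alone 5 were higher and 2 lower (camera adjusted p = 0.295). None of 13 alternative activation genes and none of 11 MHC class II and costimulation genes passed edgeR's test over all genes. At an unadjusted p under 0.05 there were 2 and 1, DESeq2 called 0 and 1, limma voom 0 and 0, and voom with sample quality weights 1 and 2. Mrc1, Clec10a, Cd300a and Chil3 were at 0.27, 0.42, 0.10 and −1.55, the last under 1 CPM. H2-Ab1, H2-Eb1, Ciita and Cd86 were at −0.55, −0.62, −0.26 and 0.18, and H2-Ab1 passed adjusted over the list alone, where 0 alternative activation genes did (camera adjusted p = 0.866 and 0.480). Under the sex covariate H2-Ab1 and H2-Eb1 were at −0.32 and −0.12, and control 1, the male control, held 94.9 CPM of H2-Eb1 against 230 to 254 CPM in the other controls. The calls of Nlrc4 and Txnip were lost with the sex covariate, at log2 fold changes no smaller than without it (0.46 and −0.32, edgeR adjusted p = 0.0583 and 0.0902), and without control 2, control 3, knockout 1 or knockout 3, and that of Txnip also without knockout 2.

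Immediate early genes, which respond within minutes to stimulation or handling, lay below other genes as a set by camera with the preset correlation (adjusted p = 0.00106) but not with an estimated correlation (adjusted p = 0.388). By fry, the adjusted p of this list was 0.044. Of 14 tested, 13 had a negative log2 fold change with a median of −0.26, and Egr1 and Ier3 fell. Ier3 went from 35.4 ± 6.05 to 23.7 ± 4.38 CPM (SD, n = 4 each; −0.58, edgeR adjusted p = 0.0445), and Egr1, a zinc finger transcription factor, from 1.38 ± 0.196 to 0.565 ± 0.132 CPM (−1.18, edgeR adjusted p = 0.0427). Knockout 4 held only 3 counts of Egr1, which is at the floor of that library. Ier2 and Atf3 were at −0.51 and −0.34, and 4 genes were lower adjusted over the list alone. With the sex covariate and GC offset together, the adjusted p by the preset was 0.201. Calls of 2 or more lists, as for the interferon and immediate early lists here, came from 19 of the 35 splits of the 8 libraries, the real split included. Among 18 ER stress and amino acid response genes Ddit3, the stress transcription factor also called CHOP, rose from 60.5 ± 2.64 to 79.6 ± 6.28 CPM (0.40, edgeR adjusted p = 0.0177), while Dnajb9 and Sdf2l1 were at −0.38 and −0.43. Adjusted over the list alone 1 was higher and 2 were lower (camera adjusted p = 0.262). Of 20 hypoxia and glycolysis genes Hk2 rose, while Gapdh fell from 338 ± 35.5 to 257 ± 24.8 CPM (−0.40) and Pgam1 from 119 ± 6.88 to 85.5 ± 15.4 CPM (−0.48). Both have many pseudogenes that can share reads. Slc2a1, the glucose transporter, was at −0.41 and passed adjusted over the list alone, where 1 gene was higher and 3 were lower (camera adjusted p = 0.393). The calls of Egr1, Ier3, Ddit3, Gapdh and Pgam1 were all lost with the sex covariate, and those of Egr1, Ier3 and Gapdh with the GC offset (edgeR adjusted p = 0.0604, 0.0546 and 0.0740). With the covariate their log2 fold changes were −1.48, −0.64, 0.33, −0.31 and −0.39 (edgeR adjusted p = 0.0788, 0.0993, 0.0816, 0.145 and 0.142), so those of Egr1 and Ier3 grew and the other 3 were somewhat nearer 0. All 5 calls were lost without control 2, control 3, knockout 2 or knockout 3. That of Egr1 was also lost without control 1, control 4 or knockout 1, that of Ier3 without control 1 or knockout 4, and that of Gapdh without control 4.

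Few genes of the lysosome, macrophage and cell cycle lists passed the test singly, and camera called none of the 4 lists with all libraries. A positive log2 fold change was found in 11 of 24 lysosome biogenesis, 10 of 17 lipid-associated macrophage, 5 of 17 macrophage identity and 8 of 30 cell cycle genes. Lysosome biogenesis genes summed to 51780 ± 4184 CPM in controls and 62550 ± 6004 CPM in knockouts (SD, n = 4 each), with Ctsb, which did not pass (edgeR adjusted p = 0.169), at 50.5% of the sum. Lipid-associated macrophage genes summed to 65620 ± 3418 and 74790 ± 3082 CPM, with Ctsb, a member of both lists, at 41.6%. Macrophage identity genes summed to 19110 ± 553 and 20450 ± 1051 CPM and cell cycle genes to 1087 ± 28.3 and 1073 ± 87.6 CPM, and none of these sums was tested. Of 24 lysosome biogenesis genes Gla, the lysosomal alpha-galactosidase, rose from 145 ± 20.7 to 198 ± 9.44 CPM (SD, n = 4 each; 0.45, edgeR adjusted p = 0.0179), and Atp6v0d2, a proton pump subunit, passed adjusted over the list alone (0.60). Gusb and Ctsa were at −0.27 and 0.27. Plin2 was the only gene of 17 lipid-associated macrophage genes called by edgeR, over all genes and over the list alone, with Ctsb, Gpnmb and Lipa at 0.30, 0.17 and 0.19. In that list voom with sample quality weights called 2 genes higher and 0 lower. Of 17 macrophage identity genes none passed edgeR's test over all genes, against 4 at an unadjusted p under 0.05, 2 called by DESeq2, 0 by limma voom and 4 by voom with sample quality weights. Fcgr3 was at 0.32 and Itgam at −0.33, and both passed adjusted over the list alone, while Adgre1 and Cx3cr1 were at 0.31 and −0.44. Itgam (−0.48, edgeR adjusted p = 0.0055) and Atp6v0d2 (0.90, edgeR adjusted p = 0.00882) passed over all genes with the sex covariate. Of 30 cell cycle genes none passed over all genes or over the list alone, against 5 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma voom and 3 by voom with sample quality weights. Mcm2, Ube2c, Ccne2 and Plk1 were at −0.69, −0.41, −0.37 and −0.40. The camera adjusted p of these lists was 0.777, 0.480, 0.855 and 0.205. The call of Gla was lost with the sex covariate at nearly the same log2 fold change (0.44, edgeR adjusted p = 0.0664) and without control 2, control 3, knockout 2 or knockout 3.

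Markers of other bone marrow cells differed widely in level, with B cell markers the highest in sum and erythroid and mast cell markers near the floor. Dendritic cell markers summed to 5.58 ± 0.949 CPM in controls and 6.23 ± 0.463 CPM in knockouts (SD, n = 4 each), erythroid markers to 0.474 ± 0.133 and 1.28 ± 0.0771 CPM, and megakaryocyte markers to 1.56 ± 0.581 and 1.11 ± 0.0567 CPM. Mast cell and basophil markers summed to 0.898 ± 0.340 and 0.635 ± 0.371 CPM, and stromal markers to 1.86 ± 1.65 CPM in controls and 2.29 CPM in knockouts, a difference smaller than the spread within controls. Neutrophil markers summed to 89.3 ± 9.88 and 106 ± 4.70 CPM, of which Csf3r made up 80.9%. Those of B cells reached 358 ± 16.8 and 437 ± 70.1 CPM, with Ighm at 66.6%, those of T and NK cells 144 ± 19.6 and 164 ± 29.1 CPM, with Il7r at 97.0%, those of monocytes 142 ± 12.6 and 201 ± 54.2 CPM, and those of osteoclasts 79.5 ± 5.96 and 85.2 ± 5.25 CPM. The single call over all genes by edgeR in these 10 lists was Car2, carbonic anhydrase, at 0.107 ± 0.0756 CPM in controls and 0.714 ± 0.305 CPM in knockouts (edgeR adjusted p = 0.0133). Controls 1 to 4 held 1, 7, 1 and 3 counts of it, a mean level below the 3-count floor of the shallowest library, so no fold is given. The call of Car2 was lost with the sex covariate and without control 3 or knockout 2. At an unadjusted p under 0.05 there were 4 monocyte, 2 osteoclast, 1 B cell and 1 neutrophil markers, and DESeq2 called 1 monocyte, 1 osteoclast and 1 B cell marker. limma voom called 1 osteoclast and 1 erythroid marker, and voom with sample quality weights 2 monocyte, 2 osteoclast, 1 neutrophil and 1 erythroid marker. Under the sex covariate edgeR called Treml4 (1.57, adjusted p = 0.0270) and Atp6v0d2 (0.90, adjusted p = 0.00882). Adjusted over the list alone, Blnk, Treml4 and Atp6v0d2 were higher as well, at 0.21, 1.04 and 0.60, and Nfatc1 was lower, at −0.30. The dendritic cell, monocyte and osteoclast lists had enough tested genes for camera, with adjusted p of 0.480, 0.750 and 0.777. Of all 20 lists tested, camera with an estimated correlation called 0, with 1 at an unadjusted p under 0.05. With the preset correlation, the inflammatory and MHC class II lists were also called without control 1 (adjusted p = 0.00378 and 0.0368), the cell cycle list without knockout 4 (0.0268) and the lipid-associated macrophage list with the sex covariate (0.0347). Among named list members that did not pass, Cxcl2, Mcm2, Ccne2, Cx3cr1, Adgre1, Clec10a and Mrc1 had log2 fold changes of −0.11, −0.34, −0.16, −0.18, 0.09, 0.11 and 0.10 under the sex covariate, all nearer 0 than without it. The median, the mean and the direction of the camera test differed in sign for the uptake and storage, alternative activation, lysosome and monocyte lists.

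**Figure D3:**
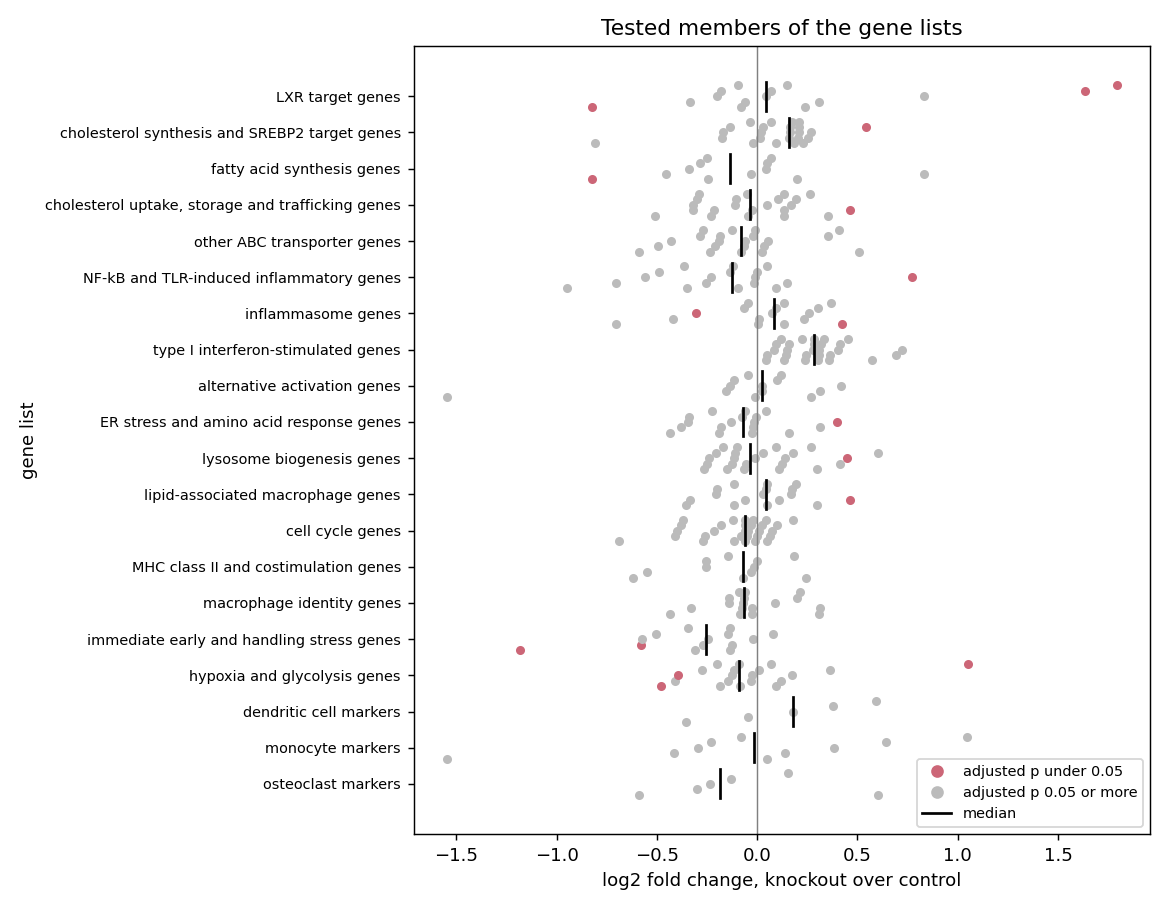
Log2 fold change, knockout over control (horizontal axis), of every tested member of the 20 gene lists with at least 5 tested genes, with members past an adjusted p of 0.05 in red and a black line at each list's median. All 28 interferon-stimulated genes lie above 0 and 13 of the 14 immediate early genes below it.

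TEC and lincRNA genes took a larger share of counts in each knockout library than in any control, although the shares did not pass after adjustment. TEC genes, which are single-exon gene models that await experimental testing, took 0.290 ± 0.0268% of counts in controls and 0.468 ± 0.0470% in knockouts (SD, n = 4 each), and lincRNA genes 0.568 ± 0.0548% and 0.805 ± 0.0665%. edgeR called 37 of 650 TEC genes higher and 0 lower, 8 of 283 lincRNA genes higher and 0 lower, and 7 of 409 antisense genes higher and 0 lower. The antisense rises were about as frequent as those among all tested genes (212 of 13857), and the share of antisense genes was not tested. At an unadjusted p under 0.05, 13, 7 and 6 were lower, and DESeq2 called 0 of each class lower, limma voom 0, 1 and 0, and voom with sample quality weights 3, 5 and 1. With the sex covariate, edgeR called 4 TEC, 3 lincRNA and 0 antisense genes higher. Among 11272 protein-coding genes 143 were higher and 160 lower. The median log2 fold change was 0.23 for TEC, 0.15 for lincRNA, 0.13 for antisense and −0.02 for protein-coding genes. The ribosomal RNA gene CT010467.1 took 3.92 ± 0.718% of counts in controls and 2.32 ± 0.424% in knockouts, and Lyz2 took 5.48 ± 0.337% and 2.50 ± 0.112%. Each of these 4 shares separated the groups, with an exact permutation p of 0.0286, the smallest possible, and 0.0715 after adjustment over 10 measures. With 4 of 10 measures at the smallest possible p, adjustment cannot bring them under 0.05. That they did not pass thus reflects the number of libraries and measures, not an overlap of the groups. Mitochondrial genes took 2.14 ± 0.179% and 2.45 ± 0.330% (exact permutation p = 0.171, adjusted p = 0.244).

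**Figure D4:**
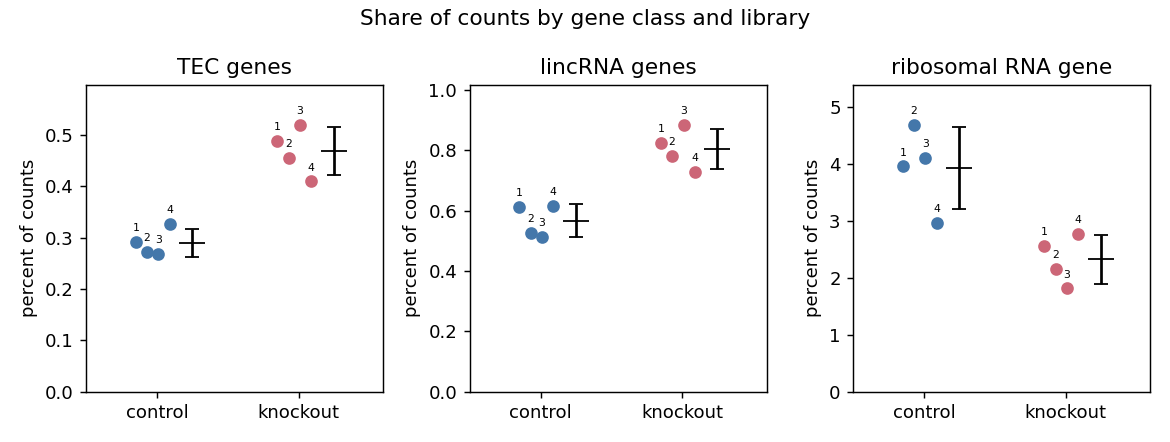
Percent of all counts (vertical axes, from 0) taken by TEC genes, lincRNA genes and the ribosomal RNA gene in each library, with points numbered by replicate and black bars for the group mean ± SD (n = 4). The knockout libraries lie above all controls for TEC and lincRNA genes and below all controls for ribosomal RNA.

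Fold changes followed GC content across protein-coding genes. The Spearman correlation across genes, which are not independent replicates, was −0.310. In the most GC-poor of 5 equal bins of genes (median 42.1%) the median log2 fold change was 0.05, with 50 genes called higher and 7 lower, and in the most GC-rich bin (median 57.3%) it was −0.17, with 5 higher and 75 lower. The correlation with transcript length was 0.0167. For single libraries the trend was measured otherwise, as the Spearman correlation of GC content with the deviation of log2 CPM from the mean of all libraries. Tested genes of every class with a mean log2 CPM above 1 were used. This correlation differed between libraries of a group, at 0.248, 0.276, 0.108 and 0.0949 in controls 1 to 4 and 0.102, −0.0429, −0.401 and −0.267 in knockouts 1 to 4. Between the groups it did not pass (exact permutation p = 0.0571, adjusted p = 0.114). With each library's GC trend removed, 207 genes were higher and 123 lower, of which 254 were among the 380.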

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

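The tests of sex and GC content on the called genes, of nuclear RNAs and of Lyz1, and the counts of genes by direction and of gene lists over other splits were chosen after the results were seen. The tests of the total number of calls over other splits, of the genes around Lyz2, of GC content on TEC genes and of genomic DNA were fixed before their results were seen.

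Within groups of 4 libraries, 17 of 242 sets of values had a highest or lowest library whose gap to its neighbour exceeded the 95% critical value of Dixon's test, where chance gives about 1 in 20. The number given for each is the gap divided by the range of its group. For genes it was taken on log2 CPM, although the level beside it is in CPM. Knockout 4, the shallowest library, was highest for Ccne2 (0.924, 11.4 CPM), Cx3cr1 (0.941, 106 CPM), Treml4 (0.907, 4.04 CPM) and the share of ribosomal protein genes (0.870, 5.51% of counts). It was lowest for Csf3r (0.859, 69.5 CPM), Itgb3 (0.839, 2.27 CPM) and the number of genes detected (0.925, 17575 genes). Control 1 was lowest for Atf3 (0.917, 98.3 CPM), H2-Eb1 (0.898, 94.9 CPM against 230 to 254 CPM), Zbtb46 (0.872, 0.365 CPM) and Dcstamp (0.871, 2.98 CPM). Control 4 was lowest for Dnajb9 (0.941, 13.5 CPM) and highest for Ctsb (0.860, 29810 CPM) and Gpnmb (0.909, 5396 CPM). Control 3 was lowest for Chil3 (0.873, 0.165 CPM), control 2 highest for Ciita (0.866, 25.6 CPM) and knockout 2 highest for Osgep (0.838, 12.5 CPM). Of the 17, 11 fell on control 1 or knockout 4, the libraries whose sex differed from the rest of their group.

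The number of called genes was weighed first. Only 1 of the 35 splits of the 8 libraries, the real one, gave as many genes, at 380 against at most 63 in any other. In the direction with more calls the real split gave 212 against at most 46, and in the other direction 168 against at most 25. These counts are parts of a single result. Chance is thus unlikely but not excluded, since 1 of 35 is the smallest share that the splits can give. The other splits also mix knockouts with controls, which can widen their spread and lower their calls. The split with 63 follows the sex of the libraries. The GC trend as a whole cause is argued against by the fold changes of the called genes. They kept a median of 0.916 (quartiles 0.815 to 0.996) of their size with the GC offset, although 126 calls were lost. With the sex covariate they kept 0.923 (0.817 to 1.05), and 312 calls were lost. That ratio could hardly have been low, since each group held both sexes and a gene that follows sex alone was unlikely to be called. The called genes thus do not follow sex alone, but a smaller part of sex in the calls stays open. Strain variants linked to the Cre insertion do not reach most calls, since 3 of 76 tested genes within 10 Mb of Lyz2 were called against 376 elsewhere (odds ratio 1.46, one-sided Fisher's exact p = 0.346). For those 3, Dctn2, Lyz1 and A130012E19Rik, they stay open. On all of chromosome 10, 25 of 656 tested genes (3.81%) were called, Lyz2 included, against 4.69% on chromosome 6. Tpgs1, Polrmt, Atp5d and Mrpl54 lie on chromosome 10 between 79669369 and 81266934, outside the window. Ddit3, also called, starts at 127290774 on the same chromosome, just past the edge of the window, so the count of 3 depends on where that edge was set. For all of these genes outside the window, linkage was not tested and stays open. The deletion itself, the Cre recombinase and the lower Lyz2 are carried by the same 4 libraries and were not separated.

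The higher TEC genes were weighed second. Removing the GC trend left them above protein-coding genes by a difference in medians of 0.179 (95% bootstrap interval 0.139 to 0.218), compared with 0.258 before, so that trend may account for a part. A larger part is not excluded, because the trend was fitted on the better expressed genes only. The bootstrap intervals in this paragraph resample genes and hold no spread between libraries. More unspliced or nuclear RNA stays open, because 6 nuclear-retained noncoding RNAs had a median log2 fold change of 0.108 (95% bootstrap interval −0.114 to 0.397), with Malat1 at 0.62 and Kcnq1ot1 at −0.12 after the GC offset. Genomic DNA also stays open, because the share of counts on 10664 protein-coding genes too low to be tested had a log2 ratio of 0.291 in the knockouts, but rested on knockout 4 at 0.0459%, the knockout with the smallest TEC share, and was 0.095 without it, with 0.0260% to 0.0319% in knockouts 1 to 3 and 0.0247% to 0.0300% in controls. An effect of the deletion on these transcripts was not separated from either.

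The rise of Lyz1 beside the fall of Lyz2 was weighed last. If a fixed share of Lyz2 reads had been counted for Lyz1, Lyz1 would have fallen with Lyz2, but its log2 fold change was 2.13 (SE 0.21), which argues against that explanation. Sequence variants of the Cre-carrying Lyz2 allele, read as Lyz1, cannot be told apart from a true rise in gene-level counts, because the rise of Lyz1 equals only 0.119% of the Lyz2 level left in the knockouts. A response of Lyz1 to the loss of Lyz2 or of the transporters was not tested.

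The number of gene lists called by camera, 2, is not beyond what other splits gave. Of the 35 splits, 19 gave at least 2 lists, the real split included. The highest other split gave 6, and it follows the sex of the libraries. The splits were compared by the number of lists alone, so they do not weigh the p-value of either list.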

How the results depend on the processing

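The sex and GC settings were chosen after seeing the data. Against 212 genes higher and 168 lower, DESeq2 gave 459 and 394, limma voom with sample quality weights 789 and 697, no filter on low counts 505 and 420, an adjusted p under 0.01 38 and 15, an absolute log2 fold change above 1 35 and 11, the sex covariate 50 and 41, and the sex covariate with the GC offset 44 and 29. limma voom, the scalings, the stricter filter, the protein-coding and Xist-free sets, 1 surrogate variable and the GC offset stayed within 1.5 times in total. Leaving out 1 library gave 39 to 404 higher and 13 to 352 lower genes, with fewer samples in each fit. The replicate block gave 91 and 83, of which 155 were among the 380. Libraries of the same number did not deviate together (correlations 0.102, 0.009, −0.028 and −0.026), so the numbers were not read as pairs.

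Without 1 library in turn, Abca1 ranged from −1.21 to −0.88 and Abcg1 from −1.74 to −1.43 in log2 fold change, with adjusted p up to 0.0692 and 0.0683. The number of gene lists called was 2, against 0 with an estimated correlation, 1 with fry, and 2 to 5 without 1 library. Without control 1, the cholesterol synthesis list was also called, and the inflammatory and MHC class II lists.

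Of 33 called named genes besides the targets, 11 stayed called whichever library was left out and 9 of these also with the sex covariate, namely Lyz2, Lyz1, Cd5l, Apoc1, Tmem154, Hk2, Mmp27, Dok2 and Insig1. The sex covariate kept 13, the GC offset 24 and both 10. No called gene changed sign in any setting. Over all settings, named genes stayed on their side of the threshold 1762 times, moved past it 119 times and fell short of it 172 times, and lists did so 348, 7 and 4 times. These counts include 24 and 17 changes of sign with neither value past the threshold. Fits without a library have fewer samples and the stricter thresholds pass fewer genes by construction. For the other differences the cause was not tested. The depth of 7609216 counts in knockout 4 limits what can be said of genes near 0.394 CPM.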

Other observations

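Everything in this part was chosen after the results were seen. Some called genes outside the naming rule also stood out, most of them at low levels. Cd38, an enzyme that consumes NAD and a known LXR target, was near the floor in controls (means of 0.0894 CPM in females and 0.0608 CPM in the male) and reached 1.39 and 1.38 CPM in female and male knockouts, a rise that passed the test (edgeR adjusted p = 0.00022). Vsig4 and Clec1b, a complement receptor and a lectin of liver macrophages, rose by 1.74 and 2.21 on the log2 scale, to 2.53 and 2.42 CPM in male knockouts (edgeR adjusted p = 0.00145 and 0.00211). Female controls held 0.784 and 0.655 CPM of them and the male control 0.608 and 0.182 CPM. The last of these is near the floor of that library (0.189 CPM), so the size of the rise of Clec1b is uncertain. Il18bp, which neutralises interleukin 18, rose by 0.72 from 33.0 CPM in female controls. The predicted gene Gm32591, also near the floor in controls (0.149 CPM in females and 0 CPM in the male), reached 6.19 and 6.07 CPM in female and male knockouts, and no fold is given for it or for Cd38. All 5 also passed with sex as a covariate.

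Genes of the respiratory chain and of mitochondrial ribosomes were not called as sets, although single members fell. Of 17 ATP synthase genes Atp5d, Atp5g3 and Atp5b fell and 0 rose, of 46 complex I genes Ndufb2 and Ndufa10 fell and 0 rose, of 22 cytochrome c oxidase and bc1 complex genes Cox8a, Cox6a1 and Cox5b fell and 0 rose, and of 78 mitochondrial ribosomal protein genes 5 fell and 0 rose, with median log2 fold changes of 0.02, 0.03, 0.05 and 0.01 (camera adjusted p = 0.851, 0.856, 0.971 and 0.884). Cytosolic ribosomal protein genes were slightly lower as a set, with 77 of 94 at a negative log2 fold change and a median of −0.09 (camera adjusted p = 8.36e-05, p = 0.310 with an estimated correlation, adjusted p = 0.354 with the sex covariate). Only Rps12 of these fell singly. The share of counts on ribosomal protein genes was 5.27 ± 0.140% in controls and 5.10 ± 0.274% in knockouts. It did not separate the groups (exact permutation p = 0.371, adjusted p = 0.464).

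Because Cd5l, Vsig4 and Clec1b are genes of Kupffer cells, the macrophages of the liver, a wider shift towards that identity was tested as a hypothesis on other Kupffer cell genes. Of 11 tested members 7 were higher, with a mean log2 fold change of 0.17 (95% bootstrap interval −0.21 to 0.56), and Spic alone passed edgeR's test (0.71, adjusted p = 0.0214). Timd4 was at 1.76 (adjusted p = 0.147) and Id1 at −1.04 (adjusted p = 0.299). By limma's camera, a test across genes rather than an exact test of libraries, the set did not stand apart from other genes (p = 0.128), which leaves the hypothesis open, since the members moved both ways and the interval reaches a rise.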
